A study of Mus musculus with 6 samples.

How the data were processed

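RNA was sequenced from mouse retinas, 3 samples injected with 1 nmol of a miR-381-3p antagomir and 3 with 1 nmol of a negative control antagomir, per the labels. Per the labels' protocols, total RNA was extracted with TRNzol and libraries were made with a SMARTER mRNA-Seq kit. The labels do not say whether the samples came from separate animals, so p-values measure the spread between these samples. Female Xist and Y-linked transcripts differed between libraries inside both groups, so neither group came from a single animal. Part of the spread may still be technical. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool and the strand setting are not given in the sources used here. Levels of overlapping, antisense or near-identical genes, such as the haemoglobin and crystallin genes, are therefore uncertain. Groups were taken from the sample titles.

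The authors deposited FPKM values (fragments scaled by gene length and a per-library total described below), with the length, position and biotype of 54532 genes, per the file headers. The control columns are named for the negative control and its number. The other 3 columns carry a letter that the labels do not explain, and were taken as the antagomir libraries because no other group remains. All directions rest on this. FPKM times gene length gave whole reads for 100% of values (tolerance 0.01 reads), so reads were rebuilt. They summed to 14377164, 16105286 and 16502352 in antagomir replicates 1, 2 and 3 and to 15200313, 15028877 and 13727596 in control replicates 1, 2 and 3. From the values, the per-library totals behind the FPKM equal median-of-ratios size factors times a common total. The size factors alternative therefore largely repeats the deposited scaling. Of the genes, 54409 were found in GENCODE release M21 for GRCm38, 98.3% of them with identical coordinates. Pairs of libraries differed by more than counting noise (chi-square per degree of freedom from 6.38 to 15.0 within groups and from 4.79 to 14.4 between them), so none was counted as a repeat.

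Genes with a mean FPKM of at least 0.5 (17453) were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2(FPKM + 1). The test was two-sided and without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on this scale and understate those of low genes. The design, the gene lists, the naming rule and the alternative settings were fixed before the data were examined. Of 789 distinct symbols in 36 lists (17 of cell types and 19 of pathways), 786 were found. Lists with at least 5 tested members (35) were tested with camera at a preset correlation of 0.01, with adjustment over lists. Camera with an estimated correlation and fry were alternatives. For lists that did not pass, ranges over the camera alternatives cover each library left out, a pseudocount of 0.1, quantile normalization, size factors, the replicate block, the added terms and estimated correlations. A list's score in a library is the mean of its members' log2 values, centred over the 6 libraries.

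Sites were searched in the longest annotated 3′ UTR of each gene in GENCODE M21, of which 99.99% followed a stop codon. Genes with CTTGTAT were compared with genes without TTGTAT within 5 bins of 3′ UTR length, and with the other 7-mers of the same bases. The difference of medians is matched on length, and camera on the site genes is not. Since no gene passed, the genes named are the 5 per direction with the smallest unadjusted p among genes with a mean FPKM of at least 1 whose groups do not overlap. Added to these were up to 2 tested members of each list with the highest mean FPKM, and Vegfa, Hif1a, Kdr, Flt1, Angpt2, Pecam1, Gfap, Meg3, Rian, Mirg and Aif1. Some genes that the rule names are not reported here. Site genes were to be named among called genes, and there were none.

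The tests were tried on simulated data with the means and spread of these libraries. With no effect put in, 0 of 17453 genes and 0 of 35 lists passed. Simulated genes were drawn independently of each other, and the spread of the most variable genes was capped. In the real data the estimated correlation inside a list reached 0.941 (lens genes). The simulation therefore cannot show how many lists camera calls when members vary together. A list shifted by 0.3 gave p = 6.30e-06 by camera and p = 0.0126 with an estimated correlation, and site genes shifted by 0.1 gave a shift of 0.0839. The alternative settings were pseudocounts of 0.1 and 0.01, no filter and a minimum of 2 FPKM, rescaling to TPM, size factors and quantile normalization. Others were eBayes without a trend or robust (statmod 1.5.0), a replicate block, array weights, voom on the rebuilt reads, an adjusted p of 0.1, an unadjusted rule, and leaving out each library. Added after seeing the data were a term for high or low Xist, a lens score as a term, leaving out the 3 libraries with lens transcripts, and a minimum mean of 10 reads with and without the restriction to protein coding genes. The fit without those 3 libraries compares 2 libraries with 1, and assumes that the lone control varies like the others. It keeps 2 Xist-low antagomir libraries and 1 Xist-high control, so it cannot tell group from sex. Sequences were handled in Python 3.11.15.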

Results

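Gene expression was measured by RNA sequencing in the retinas of mice with oxygen-induced retinopathy. In this model pups breathe high oxygen, lose part of the growing retinal vasculature and form new vessels once back in room air. Pups were moved into 75% ± 2% oxygen on postnatal day 7. On postnatal day 12 they received an injection into the vitreous of 1 nmol of an antagomir against miR-381-3p, or of 1 nmol of a negative control antagomir. An antagomir is a chemically modified antisense oligonucleotide that binds and blocks a microRNA. Retinas were taken on postnatal day 17, and each group had 3 libraries. The labels describe miR-381-3p as raised in this model and ask about its part in retinal vessel growth. Between 13727596 and 16502352 reads were assigned to genes per library. Of the 54532 genes listed, 17453 passed the expression filter and were tested. Levels are in FPKM, as mean ± SD of 3 antagomir libraries against mean ± SD of 3 control libraries. Directions rest on reading the columns that are not marked as controls as the antagomir group.

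Antagomir retinas held less Fxyd6 transcript than control retinas, without passing the test. Fxyd6 encodes a FXYD-family regulator of the sodium-potassium pump (ENSMUSG00000066705, chromosome 9, 45370185 to 45396159 in GRCm38, plus strand). It stood at 12.1 ± 0.385 against 27.1 ± 3.22 FPKM and was lower in 3 of 3 antagomir libraries. They held 747, 797 and 798 reads, against 1823, 1469 and 1584. The log2 fold change was -1.10 (SE 0.09), with adjusted p = 0.0611 by limma. Tppp, which encodes a tubulin polymerization-promoting protein, was at 12.2 ± 0.564 against 17.4 ± 0.862. The pseudogene Zfp422-ps was at 8.46 ± 0.544 against 11.6 ± 0.179. Jpt1, which encodes a microtubule-associated protein, was at 12.3 ± 0.857 against 8.22 ± 0.286. The neuropeptide Y gene Npy was at 31.2 ± 0.743 against 24.7 ± 0.785, and Tnfrsf8, which encodes the CD30 receptor, at 9.04 ± 1.255 against 5.34 ± 0.095. The log2 fold changes of these genes were -0.48 (SE 0.062) for Tppp, -0.41 (SE 0.063) for Zfp422-ps, 0.53 (SE 0.068) for Jpt1, 0.32 (SE 0.049) for Npy and 0.66 (SE 0.10) for Tnfrsf8. Their adjusted p by limma lay between 0.225 and 0.359. These are among the 5 genes per direction with the smallest p that had a mean FPKM of at least 1 and groups without overlap, and the rest of those had few reads. The pseudogene Gm44112 had 8 reads over the antagomir group and 31 over the controls, and the microRNA hairpin gene Mir6941 had 12 and 24. The ribosomal RNA gene Gm22224 had 9 reads in the antagomir group and the hairpin gene Mir7655 had 7, and both were listed at 0 in each control library.

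By limma, 0 of 17453 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1082 genes, 562 higher and 520 lower, where chance gives about 873. Over the other 9 splits of the 6 libraries into 3 and 3, which mix the groups, this count ran from 522 to 1329. The smallest p was that of the hairpin gene Mir6931 (adjusted p = 0.0611 by limma), with 6 reads in all and listed at 0 in each control library, which was named after its values were seen. Voom on rebuilt reads called 1 gene, Fxyd6, with 1109 genes at an unadjusted p under 0.05. The adjusted p of Fxyd6 by voom was 0.00312, within a range of 0.00312 to 0.694 over the alternatives. Limma called 2 genes without antagomir replicate 1, Lyz2 and Mir7655 (adjusted p = 0.0421 for both), and Fxyd6 without control replicate 2 (adjusted p = 0.0407). Lyz2 was named after its values were seen. The groups did not overlap for 2099 genes, or 12.03% of those tested, where chance gives 10%. Limma was also run on simulated data with the spread of these libraries, capped for the most variable genes, and with genes drawn independently. Among 17208 to 17238 genes it recovered 0% of 200 genes changed by 0.32 on the log2 scale. For changes of 0.58 and 1 it recovered 43.5% and 87%, with 7 and 11 unchanged genes called. The changed genes were protein coding with a mean FPKM of at least 1. All 200 changed at once, which eases the adjusted threshold, so recovery can be lower where few genes change.

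**Figure D1:**
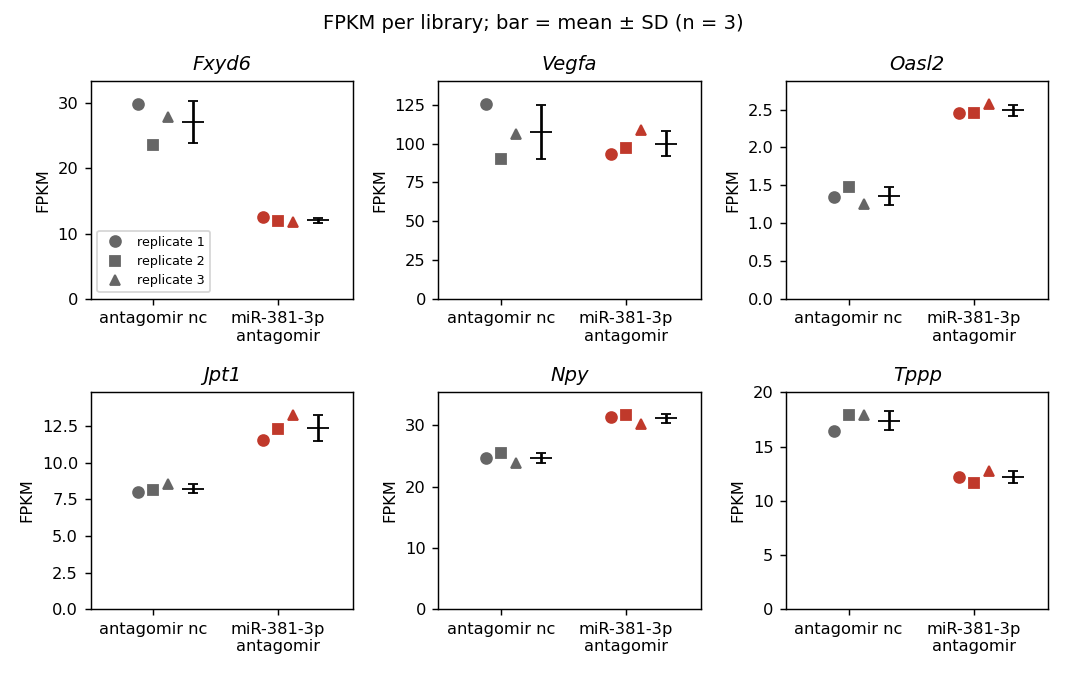
FPKM of 6 genes in each library (vertical axes start at 0), control libraries in grey and antagomir libraries in red, with marker shapes for replicate numbers and bars for the mean ± SD of 3 libraries. Fxyd6 lies between 11.8 and 12.5 FPKM in the antagomir libraries and between 23.5 and 29.8 in the controls, while the Vegfa values of the groups overlap.

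By camera on all 6 libraries without covariates, the list of pericyte genes passed and the other lists of vessel growth and hypoxia genes did not. Vegfa, the main hypoxia-driven angiogenic factor (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369 in GRCm38, minus strand), was at 100.01 ± 8.03 against 107 ± 17.5 FPKM. Its log2 fold change was -0.092 (SE 0.12), with adjusted p = 0.923 by limma (range over the alternatives 0.799 to 0.991). The 95% interval on the log2(FPKM + 1) scale spanned ratios of 0.766 to 1.15. Over the alternatives the Vegfa change ran from -0.28 without the 3 libraries with lens transcripts to 0.0248 without control replicate 1. Hif1a, an oxygen-regulated transcription factor subunit, was at 114 ± 3.27 against 109.9 ± 4.39. The VEGF receptor genes Kdr and Flt1 were at 14.6 ± 5.27 against 10.3 ± 2.19 and 4.85 ± 0.844 against 5.07 ± 0.0728. The vessel-destabilizing ligand gene Angpt2 was at 1.55 ± 0.487 against 2.12 ± 0.929, and the endothelial adhesion gene Pecam1 at 2.39 ± 0.477 against 2.17 ± 0.823. Of 28 VEGF and Notch signalling genes, 14 were higher and 14 lower (median log2 fold change 0.0048, adjusted p = 0.846 by camera). The camera direction of this list was down, while its median and mean were above 0. Endothelial markers did not pass (24 tested, median -0.063, adjusted p = 0.679), with Podxl at 45.3 ± 4.90 against 43.5 ± 0.643. The endothelial list passed without control replicate 2 (median 0.11, adjusted p = 0.00824, up) or control replicate 3 (median -0.22, adjusted p = 0.0186, down) (range over the camera alternatives 0.00209 to 0.959). Its direction turned up, without passing, when leaving out antagomir replicate 1 (median -0.0061). With the Xist-based term, added after seeing the data, the endothelial (adjusted p = 0.00209) and tip cell lists (adjusted p = 0.013) passed, with adjusted p = 0.708 for both with an estimated correlation. Tip cell genes did not pass (15 tested, median -0.083, adjusted p = 0.332), with the basement membrane genes Col4a1 at 10.99 ± 1.28 against 12.004 ± 4.62 and Col4a2 at 9.38 ± 1.6004 against 9.94 ± 3.87. The tip cell list passed without antagomir replicate 3 (median -0.26, adjusted p = 0.0417, down) or control replicate 3 (median -0.23, adjusted p = 0.00712, down) (range over the camera alternatives 0.00712 to 0.954). Its direction turned up, without passing, when leaving out control replicate 2 (median 0.08). HIF target genes did not pass (28 tested, median -0.05, adjusted p = 0.433), with the glycolytic genes Aldoa at 601 ± 23.3 against 624 ± 42.9 and Eno1 at 470.0 ± 24.3 against 475 ± 61.2. The HIF target list passed without control replicate 2 (median -0.079, adjusted p = 0.0419, down) (range over the camera alternatives 5.48e-05 to 0.927). Its direction turned up, without passing, when leaving out antagomir replicate 1 (median 0.027) or control replicate 1 (median 0.016). With the lens score as a term, added after seeing the data, the HIF target list passed (adjusted p = 5.48e-05, and adjusted p = 0.27 with an estimated correlation). Wnt, TGF-beta and Norrin genes did not pass (26 tested, median -0.035, adjusted p = 0.656), with Ctnnb1 at 61.3 ± 7.09 against 63.1 ± 1.71 and Tgfb2 at 14.3 ± 0.656 against 12.7 ± 0.363. Pericyte and smooth muscle markers fell by camera, with 8 of 9 lower (median -0.081, adjusted p = 0.0452 by camera, and adjusted p = 0.713 with an estimated correlation). Vtn was at 254 ± 26.7 against 259 ± 19.0 and Ndufa4l2 at 29.96 ± 0.625 against 38.1 ± 11.5. The pericyte call was lost without antagomir replicate 1 (median -0.069, adjusted p = 0.127), antagomir replicate 2 (median -0.065, adjusted p = 0.0717), control replicate 1 (median -0.11, adjusted p = 0.0928) or control replicate 2 (median -0.012, adjusted p = 0.289) (range over the alternatives 0.0023 to 0.927). It was also lost with a pseudocount of 0.1 (median -0.10, adjusted p = 0.0509), with quantile normalization (median -0.065, adjusted p = 0.0562) and without the 3 libraries with lens transcripts (median -0.091, adjusted p = 0.125). The pericyte median was -0.12 without antagomir replicate 3 and -0.19 without control replicate 3. It was -0.26 with a minimum of 2 FPKM and -0.13 with the Xist-based term.

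Interferon-stimulated genes rose as a group by camera. Of 25 tested members, 23 were higher and 2 lower, with a median log2 fold change of 0.25 (adjusted p = 1.58e-06 by camera, and adjusted p = 0.695 with an estimated correlation). At an unadjusted p under 0.05, 6 were higher and 0 lower. Fry gave adjusted p = 0.0013 for change in either direction and adjusted p = 0.346 for change in 1 direction. The list score was 0.18, 0.16 and 0.057 in the antagomir libraries and -0.044, -0.17 and -0.18 in the controls. The exact two-sided permutation p of the score was 0.1, the smallest that 3 against 3 libraries can give. Oasl2, of the oligoadenylate synthetase-like family and named after its values were seen, was at 2.49 ± 0.0689 against 1.36 ± 0.114 FPKM. It was the 1 member that passed adjusted over the list alone (adjusted p = 0.012 by limma), against 0 members over all genes tested (adjusted p = 0.38). Stat2, a signalling factor of this response, was at 8.56 ± 0.258 against 8.18 ± 0.124, and the ubiquitin ligase gene Trim25 at 6.75 ± 0.401 against 6.80 ± 0.486. The list's median was 0.073 with a minimum of 2 FPKM, which leaves out low members (adjusted p = 0.0392), and 0.37 with a pseudocount of 0.1 (adjusted p = 1.49e-06) (range over the alternatives 4.79e-07 to 0.927). Its call held without any single library, and was lost without the 3 libraries with lens transcripts, a fit added after seeing the data with 2 libraries against 1 (median 0.10, adjusted p = 0.0651).

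Complement genes and microglia markers rose by camera, with the highest scores of both lists in antagomir replicate 2. Both lists hold C1qa, C1qb and C1qc, so their calls are not independent. Complement genes were higher in 10 of 12 members (median 0.43, adjusted p = 7.87e-04 by camera, and adjusted p = 0.713 with an estimated correlation). Their score was -0.087, 0.74 and 0.027 in the antagomir libraries and -0.15, -0.30 and -0.22 in the controls, and the median was 0.18 without antagomir replicate 2. C1qb and C1qa, which encode subunits of the first complement component, were at 19.5 ± 6.89 against 12.3 ± 2.91 and 18.5 ± 7.63 against 12.4 ± 1.26 FPKM. Microglia and macrophage markers were higher in 19 of 25 members (median 0.30, adjusted p = 4.26e-04 by camera, and adjusted p = 0.827 with an estimated correlation). The lysosomal protease gene Ctss was at 32.1 ± 16.3 against 16.3 ± 3.65, and Aif1, which encodes the microglial protein IBA1, at 2.08 ± 1.30 against 0.994 ± 0.165. The microglia score was 0.53 in antagomir replicate 2, against -0.22 and 0.16 in the other antagomir libraries and -0.092, -0.23 and -0.15 in the controls. The microglia call was lost without antagomir replicate 2 (median 0.027, adjusted p = 0.102) (range over the alternatives 1.54e-10 to 0.954). With the lens score as a term the microglia median was 0.18 (adjusted p = 0.0108). Cd74, the invariant chain of antigen presentation, named after its values were seen, was at 1.75 ± 0.602 against 0.326 ± 0.164. It passed adjusted over the list alone (adjusted p = 0.0234 by limma), and not over all genes tested (adjusted p = 0.527). Inflammatory cytokine and NF-kB genes did not pass (9 tested, median 0.10, adjusted p = 0.516 by camera). Among them Tnfaip3, an inhibitor of NF-kB signalling, was at 28.7 ± 2.38 against 36.3 ± 0.964 and Nfkbia at 12.5 ± 2.01 against 10.9 ± 1.03. Tnfaip3 passed as lower adjusted over the list alone (adjusted p = 0.0188 by limma), and not over all genes tested (adjusted p = 0.641). The T cell, B cell and neutrophil list had 3 tested members, too few for a test, with Cd8a at 0.867 ± 0.117 against 0.911 ± 0.327 and Camp at 0.481 ± 0.211 against 0.755 ± 0.273.

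Reactive gliosis genes did not pass (26 tested, median 0.31, adjusted p = 0.0585 by camera). Gfap, the intermediate filament of stressed Müller glia and astrocytes, was at 21.2 ± 14.8 against 25.7 ± 8.98 FPKM, and ranged from 12.4 to 38.3 inside the antagomir group. The metallothionein gene Mt1 was at 185 ± 159.5 against 140.2 ± 62.8, and Cryab, which encodes a small heat shock protein also abundant in lens, at 30.1 ± 11.4 against 51.8 ± 40.9. The gliosis list passed without antagomir replicate 1 (median 0.49, adjusted p = 0.00366, up), antagomir replicate 3 (median 0.61, adjusted p = 0.00352, up) or control replicate 1 (median 0.51, adjusted p = 0.0042, up) (range over the camera alternatives 0.00352 to 0.954). Its direction turned down, without passing, when leaving out antagomir replicate 2 (median -0.15). The acute-phase genes Lcn2 and Serpina3n, chosen after their values were seen, were highest in antagomir replicate 2. Lcn2 was at 85.4 FPKM there against 2.81 to 12.2 in the other libraries, and Serpina3n at 72.8 against 3.93 to 14.2. Homeostatic markers of Müller glia and astrocytes did not pass (21 tested, median -0.06, adjusted p = 0.516). The glutamine synthetase gene Glul was at 417 ± 25.9 against 467 ± 69.2 and Apoe at 352 ± 60.2 against 285 ± 38.8. Immediate early genes, which respond rapidly to stimulation, rose by camera, with 21 of 23 higher (median 0.26, adjusted p = 2.43e-06 by camera, and adjusted p = 0.713 with an estimated correlation). The median was 0.40 without antagomir replicate 1 and 0.16 without antagomir replicate 3. Ier3 was at 68.0 ± 6.15 against 57.5 ± 4.14 and Btg2 at 53.9 ± 4.08 against 47.1 ± 0.956. Fos and Egr1, chosen after their values were seen, were highest in antagomir replicate 3. Fos was at 52.2 FPKM there against 12.1 to 33.6 in the other libraries, and Egr1 at 78.1 against 10.5 to 21.4.

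Among neuronal genes, those of retinal ganglion cells, synapses and amacrine cells fell by camera. Ganglion cell markers were lower in 19 of 22 members (median -0.19, adjusted p = 7.42e-05 by camera, and adjusted p = 0.827 with an estimated correlation). The gamma-synuclein gene Sncg was at 90.9 ± 15.0 against 101 ± 16.9 FPKM and the neurofilament gene Nefl at 75.0 ± 3.94 against 85.4 ± 11.6. The ganglion cell median was -0.12 without antagomir replicate 2, -0.30 without control replicate 1 and -0.10 without control replicate 3, and -0.12 with the lens score as a term. Synaptic genes were lower in 21 of 28 (median -0.12, adjusted p = 7.29e-04 by camera, and adjusted p = 0.713 with an estimated correlation). The vesicular glutamate transporter gene Slc17a7 was at 299 ± 24.8 against 296 ± 19.5 and the complexin gene Cplx4 at 251 ± 21.3 against 264 ± 28.8. Without the 3 libraries with lens transcripts, the calls of ganglion cell markers (median 0.0103) and synaptic genes (median -0.053) were lost. That fit compares Xist-low antagomir libraries with a lone Xist-high control. Amacrine markers were lower in 17 of 22 (median -0.068, adjusted p = 0.0452 by camera, and adjusted p = 0.862 with an estimated correlation). Calb2, a calcium-binding protein gene, was at 149 ± 13.1 against 168 ± 21.9 and the gap junction gene Gjd2 at 46.3 ± 1.31 against 47.3 ± 2.85. The amacrine call was lost without antagomir replicate 2 (median -0.041, adjusted p = 0.455) or control replicate 2 (median 0.0043, adjusted p = 0.835) (range over the alternatives 0.00341 to 0.963). It was also lost with a minimum of 2 FPKM (adjusted p = 0.0685), with the lens score as a term (median -0.022, adjusted p = 0.28) and without the 3 libraries with lens transcripts (median -0.023, adjusted p = 0.963). Npy, of the same list, was higher and passed adjusted over the list alone (adjusted p = 0.00783 by limma), and not over all genes tested (adjusted p = 0.359). Rod markers did not pass (26 tested, median 0.0026, adjusted p = 0.882), with the rod transducin gene Gnat1 at 2369.8 ± 133 against 2393 ± 119.8. The rod list passed without control replicate 1 (median 0.057, adjusted p = 0.0151, up) (range over the camera alternatives 0.0151 to 0.996). Its direction turned down, without passing, when leaving out antagomir replicate 3 (median -0.00064), control replicate 2 (median -0.024) or control replicate 3 (median -0.0023). Cone markers did not pass (15 tested, median -0.076, adjusted p = 0.144), with Gnb3 at 240.3 ± 72.5 against 191 ± 27.3 and the opsin gene Opn1sw at 169 ± 11.4 against 186 ± 26.2. The cone list passed without control replicate 2 (median -0.09, adjusted p = 0.0366, down) (range over the camera alternatives 0.0366 to 0.954). Its direction turned up, without passing, when leaving out control replicate 1 (median 0.025). Bipolar cell markers did not pass (22 tested, median -0.0068, adjusted p = 0.832), with the transcription factor gene Otx2 at 63.9 ± 4.24 against 57.3 ± 1.79. Horizontal cell markers did not pass (11 tested, median 0.081, adjusted p = 0.285), with Ndrg1 at 50.5 ± 7.88 against 40.1 ± 1.47 and Sept4 at 36.9 ± 2.37 against 38.0 ± 4.08. The horizontal cell list passed without control replicate 2 (median 0.078, adjusted p = 0.0315, up) (range over the camera alternatives 0.0315 to 0.954). The rod list had a mean below 0 with a median and test pointing up, and the bipolar list a median below 0 with a mean and test pointing up.

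Among genes of energy metabolism, mitochondrially encoded protein and ribosomal RNA genes and glycolysis enzymes fell and nuclear oxidative phosphorylation genes rose by camera. The mitochondrially encoded protein and ribosomal RNA genes were lower in 15 of 15 members (median -0.20, adjusted p = 5.73e-05 by camera, and adjusted p = 0.728 with an estimated correlation). The cytochrome oxidase gene mt-Co1 was at 3676 ± 97.4 against 4241 ± 612 FPKM and mt-Cytb at 2492 ± 189 against 2715 ± 357. Of 17 tested mitochondrial tRNA genes, outside the list and examined after their values were seen, 6 were higher and 11 lower. By limma and by voom 0 of them passed, with 2 higher and 3 lower at an unadjusted p under 0.05, and the smallest adjusted p was that of mt-Tm (adjusted p = 0.544 by limma), which was higher and listed at 0 in each control library. The mitochondrial share of reads was 1.604%, 1.64% and 1.52% in the antagomir libraries and 2.03%, 1.66% and 1.66% in the controls, and the list median was -0.078 without control replicate 1 and -0.45 without the 3 libraries with lens transcripts. Nuclear oxidative phosphorylation genes rose by camera, with 27 of 36 higher (median 0.052, adjusted p = 0.00768 by camera, and adjusted p = 0.862 with an estimated correlation). The ATP synthase genes Atp5b and Atp5a1 were at 220.4 ± 2.91 against 214 ± 5.64 and 187 ± 1.40 against 192 ± 3.53. The nuclear call was lost without control replicate 2 (median 0.031, adjusted p = 0.377) or control replicate 3 (median 0.034, adjusted p = 0.0804) (range over the alternatives 2.71e-07 to 0.954). The nuclear median was 0.10 without control replicate 1. The nuclear call was also lost with quantile normalization (adjusted p = 0.0573), with the lens score as a term (adjusted p = 0.186) and without the 3 libraries with lens transcripts (median -0.048, adjusted p = 0.172). Glycolysis enzymes fell by camera, with 15 of 21 lower (median -0.088, adjusted p = 0.0121 by camera, and adjusted p = 0.713 with an estimated correlation), and the pyruvate kinase gene Pkm was at 507 ± 18.2 against 541 ± 59.0. The glycolysis call was lost without antagomir replicate 1 (median -0.026, adjusted p = 0.451) or control replicate 1 (median -0.0073, adjusted p = 0.138) (range over the alternatives 4.41e-06 to 0.927). Antioxidant and iron genes did not pass (21 tested, median -0.02, adjusted p = 0.832), with the ferritin gene Fth1 at 528 ± 33.0 against 505 ± 16.3 and Gpx4 at 205 ± 8.60 against 192 ± 27.8. Endoplasmic reticulum stress genes did not pass (22 tested, median 0.076, adjusted p = 0.174), with Atf4 at 125 ± 13.7 against 108 ± 4.43 and Calr at 98.7 ± 10.3 against 90.1 ± 10.7. The stress list passed without antagomir replicate 1 (median 0.15, adjusted p = 0.0108, up) (range over the camera alternatives 0.0108 to 0.954). Cell cycle genes did not pass (18 tested, median -0.015, adjusted p = 0.574), with Pcna at 26.7 ± 1.08 against 25.5 ± 1.65 and Ccna2 at 8.11 ± 1.39 against 7.97 ± 0.777. The p53 and apoptosis list did not pass by camera (19 tested, median 0.061, adjusted p = 0.0546), and passed fry's test for change in either direction (adjusted p = 0.00991). Gadd45a was at 23.7 ± 2.20 against 21.5 ± 2.31 and Ccng1 at 20.7 ± 1.16 against 20.98 ± 0.13. The p53 list passed without antagomir replicate 3 (median 0.10, adjusted p = 0.0159, up) (range over the camera alternatives 0.0159 to 0.927).

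Transcripts of tissues beside the retina differed between libraries of both groups. Lens transcripts were abundant in antagomir replicate 1 and control replicates 2 and 3. The alpha-crystallin gene Cryaa reached 99.0, 244 and 82.9 FPKM there, against 0.0474 to 1.37 in the other libraries. Lens crystallin and fibre genes lay lower with the antagomir in 23 of 23 members (median -1.59, adjusted p = 7.87e-04 by camera, and adjusted p = 0.862 with an estimated correlation). Crygb was at 52.5 ± 87.9 against 108 ± 95.4 and Cryaa at 33.5 ± 56.8 against 109 ± 124. The lens call was lost without antagomir replicate 2 (median -0.87, adjusted p = 0.0659), antagomir replicate 3 (median -0.62, adjusted p = 0.145) or control replicate 2 (median -0.41, adjusted p = 0.417) (range over the alternatives 6.45e-13 to 0.954). The lens median was -2.83 without antagomir replicate 1, -3.13 without control replicate 1 and -0.94 without control replicate 3, and 0.19 without the 3 libraries with lens transcripts. Red blood cell genes fell by camera in 5 of 5 members (median -1.20, adjusted p = 7.29e-04 by camera, and adjusted p = 0.713 with an estimated correlation). The haemoglobin genes Hbb-bs and Hba-a1 were at 20.8 ± 11.3 against 75.9 ± 50.4 and 11.6 ± 7.33 against 32.4 ± 21.5. Control replicate 1 held the highest Hbb-bs level (134 FPKM), and the erythrocyte median was -0.62 without control replicate 1 and -2.23 without the 3 libraries with lens transcripts. Pigment epithelium markers did not pass (16 tested, median -0.095, adjusted p = 0.375), with Krt18 at 76.4 ± 13.7 against 63.6 ± 4.13 and Ttr at 49.8 ± 16.4 against 36.8 ± 12.8. The pigment epithelium list passed without control replicate 1 (median -0.21, adjusted p = 0.0181, down) (range over the camera alternatives 0.0181 to 0.954). Its direction turned up, without passing, when leaving out antagomir replicate 2 (median 0.016) or control replicate 2 (median -0.053). Cornea, ciliary body and iris markers did not pass (9 tested, median -0.20, adjusted p = 0.139), with Col9a1 at 29.5 ± 7.01 against 33.0 ± 10.8 and Tfap2b at 27.9 ± 2.18 against 27.4 ± 2.52. The cornea list passed without antagomir replicate 3 (median -0.22, adjusted p = 0.0396, down), control replicate 1 (median -0.34, adjusted p = 0.0066, down) or control replicate 3 (median -0.30, adjusted p = 0.0353, down) (range over the camera alternatives 0.0066 to 0.954). Its direction turned up, without passing, when leaving out control replicate 2 (median 0.093). Striated muscle markers did not pass (5 tested, median 0.025, adjusted p = 1), with Mylpf at 2.76 ± 0.956 against 2.63 ± 0.516 and Actc1 at 2.11 ± 0.64 against 2.19 ± 0.349. Extracellular matrix genes did not pass (25 tested, median 0.0046, adjusted p = 0.574), with Sparc at 129.6 ± 4.51 against 145 ± 10.3 and Col6a1 at 25.3 ± 2.14 against 22.4 ± 0.174. For muscle and matrix the median was above 0 and the mean and test pointed down. Xist, which is expressed from the inactive X chromosome of females, was at 224, 234 and 248 FPKM in antagomir replicate 1 and control replicates 1 and 3. The Y-linked gene Eif2s3y was listed at 0 in those libraries and at 36.2 to 40.5 in the other 3. Both genes were chosen after their values were seen, and the labels give no sex. Without the 3 libraries with lens transcripts, Xist-low antagomir libraries were compared with a lone Xist-high control. A change in that fit cannot be told apart from a difference of sex.

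Of 35 lists, 13 passed camera with the preset correlation, 5 up and 8 down. With an estimated correlation 0 passed (smallest adjusted p = 0.695), by fry 0 passed in 1 direction and 2 in either direction. The score separated the groups for 2 lists, interferon-stimulated and complement genes, where chance gives 3.5. Adjusted over the list alone, limma called 4 members (Oasl2, Cd74, Npy and Tnfaip3), against 0 of 642 members over all genes tested by limma (53 with an unadjusted p under 0.05) and 0 by voom. With the Xist-based term 17 lists passed by camera, the cornea (adjusted p = 0.0278) and p53 lists (adjusted p = 0.0237) among them, and 0 with an estimated correlation (adjusted p = 0.708 for both). With the lens score as a term 12 passed, the cone list (adjusted p = 0.0374) among them, and 0 with an estimated correlation (adjusted p = 0.954 for cones). Both terms were added after seeing the data. Leaving out a single library turned the camera direction, without a pass, of the VEGF and Notch, Müller glia, bipolar, muscle, matrix, NF-kB, antioxidant, Wnt, Dlk1-Dio3 and microRNA biogenesis lists.

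**Figure D2:**
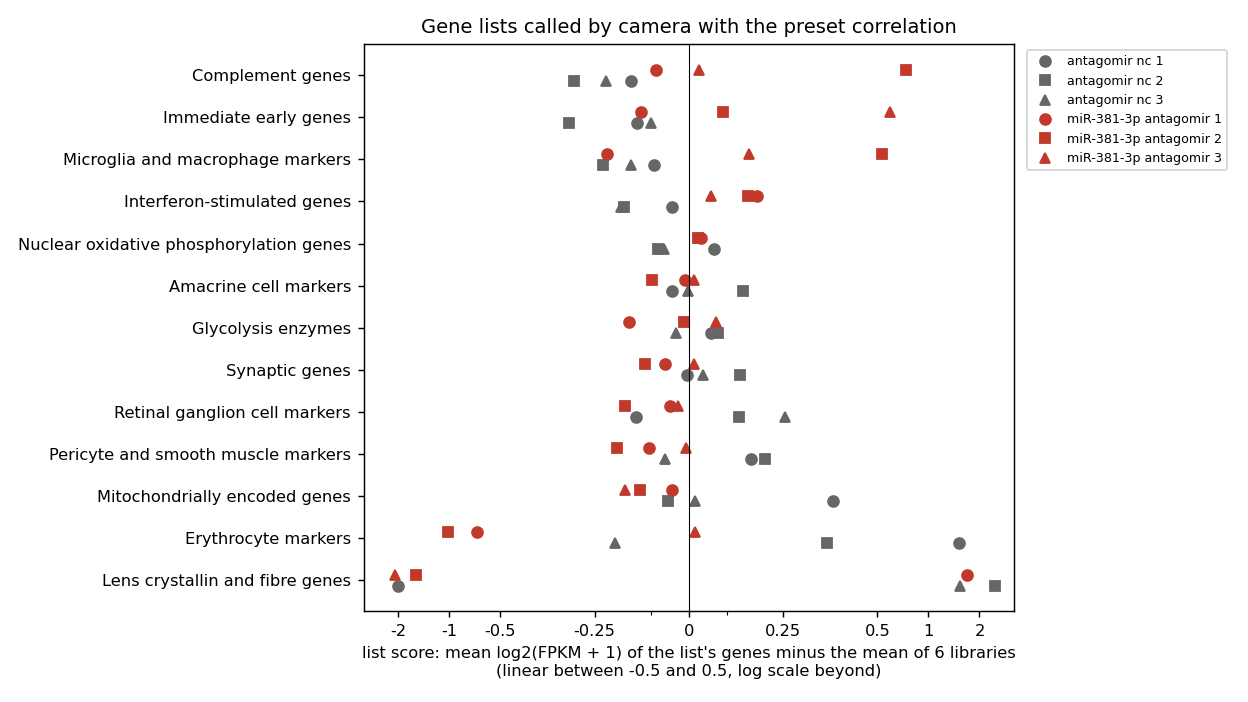
Score of each of the 13 gene lists that passed camera with the preset correlation, in each library (horizontal axis, mean log2(FPKM + 1) of the members minus the mean over 6 libraries, linear near 0 and logarithmic beyond), control libraries in grey and antagomir libraries in red, with marker shapes for replicate numbers. The interferon and complement scores of the 3 antagomir libraries lie above those of the controls, and the lens scores form clusters that mix the groups.

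Genes with miR-381-3p sites were slightly lower after the antagomir. Blocking a microRNA would raise its targets. Of 13172 tested genes with an annotated 3′ UTR, 1709 held the 7-base site CTTGTAT, 481 of them as part of the 8-base site, and 7559 held no 6-base match. Within bins of like 3′ UTR length, the median log2 fold change of genes with a site lay -0.0194 from that of genes without one, and -0.0439 from it without the bins. Camera compared the site genes with all other genes with a 3′ UTR and was not matched on its length. It gave p = 0.00672 for a lower site set, and p = 0.036 with an estimated correlation. The exact two-sided permutation p of the length-matched shift was 0.3. The shift was -0.00562 without control replicate 3, where camera did not pass, -0.00869 without control replicate 1, -0.0331 without control replicate 2 and -0.00828 with an added Xist-based term. Among 209 other 7-mers made of the same bases the shifts ran from -0.0262 to 0.00198, and 181 were at least as high. By limma 0 of 1709 site genes passed, and 87 had an unadjusted p under 0.05, 25 of them higher. Over all 17453 genes tested 1082 had such a p, 562 of them higher. No like count was made for genes of similar 3′ UTR length. The microRNA lies in the imprinted Dlk1-Dio3 cluster, whose list did not pass (6 tested, median 0.017, adjusted p = 0.832, with a mean below 0 and a median and test pointing up). Its noncoding RNA genes Meg3, Rian and Mirg were at 83.7 ± 5.48 against 88.9 ± 11.97, 11.6 ± 0.589 against 11.6 ± 1.11 and 1.37 ± 0.0419 against 1.34 ± 0.187 FPKM, and Begain at 30.5 ± 2.49 against 27.8 ± 1.38. MicroRNA biogenesis and silencing genes did not pass (16 tested, median -0.0058, adjusted p = 0.846), with Ran at 46.2 ± 1.36 against 46.4 ± 4.06 and Zswim8 at 33.3 ± 2.97 against 33.2 ± 2.42. The hairpin gene Mir381 had 2 reads in antagomir replicate 2 and 1 in replicate 3, and was listed at 0 in the other libraries. The level of the mature microRNA was not analysed here.

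**Figure D3:**
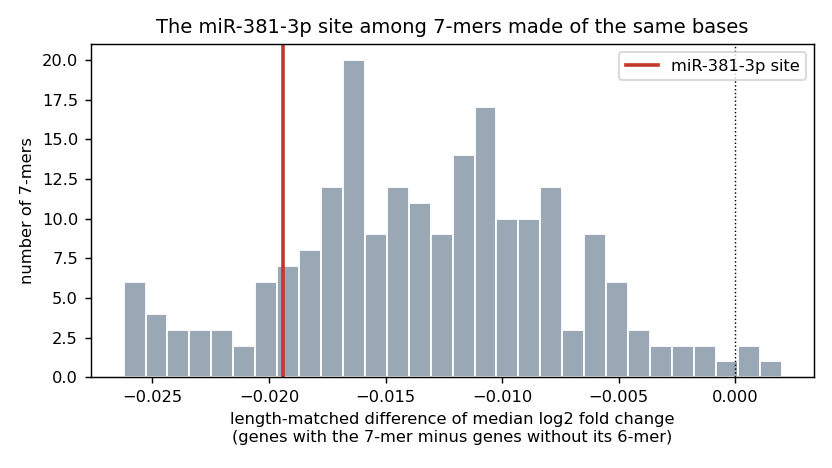
Distribution of the length-matched difference of median log2 fold change (horizontal axis) over 209 other 7-mers made of the same bases as the miR-381-3p site (vertical axis, number of 7-mers), with the site as a red line at -0.0194. Most of the other 7-mers also lie below 0.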

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

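The Xist and lens terms, the fit without the lens-transcript libraries and the read minimums were chosen after seeing the data. The 10 genes of smallest p among those with a mean FPKM of at least 1 and no overlap of the groups kept direction and side of the threshold in 211 of 218 refits and passed it in 7, 5 of them for Fxyd6 (-1.19 to -1.10 in these, -1.26 to -1.03 over all its refits). Of 91 other genes refitted, 1995 of 2069 refits moved by under 1 SD, and 99 changed sign (55 without a single library) in 37 genes, none past the threshold. The count of genes called, 0, became 5 without the trend (3 higher, 2 lower), 2 with array weights (1 and 1), 1 by voom (lower), 3 at an adjusted p of 0.1 (1 and 2), 68 by the unadjusted rule with a log2 fold change of at least 1 (38 and 30), and 1 with a mean of at least 10 reads, with or without the restriction to protein coding genes (lower, Fxyd6). Without single libraries it was 0 to 2, with 0 to 2 higher and 0 to 1 lower. Genes called without the trend had 39 reads or fewer in all, and the read minimums tested fewer genes. Lists called, 13, became 0 with an estimated correlation, 0 by fry in 1 direction and 2 in either, and 9 to 16 without single libraries. Camera then estimates the correlation from 6 libraries, and fry tests each list against no change. The 13 lists kept their call in 153 of 220 refits, lost it with the same direction in 63 and lost it with the other direction in 4. Without the lens-transcript libraries medians changed sign for nuclear oxidative phosphorylation (-0.048), ganglion cell (0.0103) and lens genes (0.19), and without control replicate 2 for amacrine genes (0.00429). The fit without the lens-transcript libraries also compared Xist-low antagomir libraries with a lone Xist-high control. Its changes therefore cannot be put down to lens transcripts alone. Camera on the site genes, which was not matched on length, missed the threshold without control replicate 3. The length-matched seed-site shift ran from -0.0331 to -0.00562 over single libraries and was -0.0343 without the lens-transcript libraries. Vegfa changed sign without control replicate 1 (range over single libraries -0.209 to 0.0248) and was -0.28 without the lens-transcript libraries, with adjusted p of 0.799 to 0.991 over alternatives. For these the cause was not tested. Same-numbered libraries did not deviate together (correlations -0.194, -0.102, -0.137; none correlated best with its own number), so they share only a number. With a replicate block 0 genes were called (856 at an unadjusted p under 0.05), the shift was -0.0194, Vegfa -0.0921, and 13 lists were called, with amacrine cells lost (adjusted p = 0.0717) and gliosis gained (adjusted p = 0.0476), and with an estimated correlation 0 were called (smallest adjusted p = 0.927, for gliosis too). Depth limits genes of a few reads, such as hairpin genes.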

Other observations

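Of the tests in this part, those with the Xist-based, microglia and lens terms or without the libraries with lens transcripts, of cell type quartiles, of reads in other genes, of 7-mers with a shift as low, and of splits for the counts and the interferon list were chosen only after the result was seen. The calprotectin gene S100a9 and the lysozyme gene Lyz2, chosen after their values were seen, were higher in 3 of 3 antagomir libraries. Lyz2 was at 12.7 ± 6.28 against 4.62 ± 0.383 FPKM. S100a9 was at 0.922, 1.06 and 0.813 in the antagomir libraries, and at 0.129 and 0.139 in control replicates 1 and 3, with replicate 2 listed at 0. Their adjusted p by limma was 0.38 for S100a9 and 0.801 for Lyz2. The metalloreductase gene Steap4 (2.24 ± 2.53 against 0.106 ± 0.0732) and the complement gene C3 (2.76 ± 2.30 against 0.53 ± 0.255) were highest in antagomir replicate 2, with adjusted p = 0.802 and 0.801 by limma.

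Fxyd6 was lower in all 3 antagomir libraries. Unequal sexes are argued against, since with the Xist-based term its log2 fold change was -1.04 (95% interval -1.21 to -0.86, adjusted p = 0.156 by limma). The interval does not allow for the choice of this gene by its small p. The ratio was 0.433 among Xist-high libraries, where antagomir replicate 1 stood alone for its group. Among Xist-low libraries it was 0.504, where control replicate 2 stood alone. Loss of a whole class of retinal neurons is argued against by the lowest lower quartile over their lists, -0.248 (ganglion cells). It lies above the upper limit of the Fxyd6 change (-0.88). Over 11 cell type lists the lowest was -0.296, for pericyte and smooth muscle markers with 9 tested. That list does not decide for rarer cells, since the scale understates changes of low genes. Its median was -0.26 with a minimum of 2 FPKM. Astrocytes shared a list with Müller glia, so their loss was not tested. Reads given to related or near genes are argued against, since the other Fxyd genes and the genes within 50 kb changed by -4.34% of the 936 reads that Fxyd6 lacked. Similar sequences elsewhere and reads left unassigned were not examined. A strain variant, a loss of a cell subtype or of a rarer cell type and an effect of the antagomir stay open as untested hypotheses. Fxyd6 missed the threshold by limma (adjusted p = 0.0611).

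Interferon-stimulated genes were higher with the antagomir, with a median of 0.25, and of 0.073 with a minimum of 2 FPKM. With the microglia and macrophage score as a term the median was 0.263 (adjusted p = 8.54e-07 by camera), and with the Xist-based term 0.242 (adjusted p = 4.79e-07). The size of the rise thus did not follow the microglia score or Xist. The camera calls add little, since 5 of 10 splits gave as many list calls as the real one. With the Xist-based term and an estimated correlation the call was lost (adjusted p = 0.708 by camera). An estimated correlation was not tried with the microglia term. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave a median as large, the real one, and the highest other was 0.174, but 10 splits are too few for a share under 0.05. A different response to the oligonucleotides may be the source and was not tested. The call was lost with an estimated correlation (adjusted p = 0.695 by camera) and without the libraries with lens transcripts (median 0.10). In the fit without those libraries, group and Xist level coincided.

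Genes with miR-381-3p sites were slightly lower with the antagomir, the reverse of what release from the microRNA would give. A candidate explanation is a shift of long 3′ UTRs rich in the same bases, since 13.4% of the other 7-mers had a shift as low. Site genes had a median 3′ UTR of 2556 bases, against 702 in genes without a 6-base match, and without matching on length the shift was -0.0439. Over the 10 splits, 3 gave an absolute shift as large as the real 0.0194, too few splits for a share under 0.05. The highest other, 0.0338, came from the split of Xist-high from Xist-low libraries, and with the Xist-based term the shift was -0.00828.

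For the counts the 10 splits are also too few for a share under 0.05. The real split called 0 genes, so all 10 reach its count by construction and that comparison decides nothing. The highest other, 19, came from antagomir replicate 1 with control replicates 2 and 3, the libraries with lens transcripts. Of those 19, 17 were on the lens list. The split of Xist-high from Xist-low libraries called 10, 9 of them X- or Y-linked. The counts of these splits mostly restate the lens and sex-linked transcripts by which the libraries were told apart, so they are no evidence of a further structure. With terms for the lens and sex-linked transcripts, limma called 0 genes. At an unadjusted p under 0.05 there were 1000 for the Xist-based term and 845 for the lens score. Antagomir replicates 1 and 2 with control replicate 3 called Mir7682 alone (6 reads in all, adjusted p = 0.0231 by limma). Antagomir replicates 1 and 3 with control replicate 2 called Gm22079 alone (20 reads in all, adjusted p = 0.0299 by limma). Both adjusted p lie below that of Fxyd6 in the real split (adjusted p = 0.0611 by limma). For lists, 5 of 10 splits gave as many calls by camera as the real 13, and the highest other gave 16, reached by the split of the libraries with lens transcripts and by 1 more. With the lens score as a term 12 lists passed by camera, and 0 with an estimated correlation (smallest adjusted p = 0.27).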
